A study of Mus musculus with 16 samples.

How the data were processed

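The counts are reads per gene and library as the authors deposited them, in 1 table of 16 libraries. Per the labels' protocols, cells were sorted from pooled mouse peripheral lymph nodes after removal of lineage-positive cells, complementary DNA was made with the SMART-Seq v4 kit and libraries with the Nextera kit. Reads were mapped to the mm10 genome with TopHat 1.4.1, sorted with SAMtools and counted with HTSeq 0.6.0. These libraries hold sorted populations, not single cells, and the preparation does not keep the strand, so reads from overlapping or antisense genes, paralogs and pseudogenes are uncertain.

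The table holds 23337 gene symbols, of which 22855 matched 1 gene of the GRCm38 annotation, and 6727 had no count in any library. It holds no mitochondrial genes and 1 T cell receptor segment, so neither class could be read. Total counts ran from 20476092 to 45786417. Genes were kept with filterByExpr by group (minimum count 10), which left 13328. Libraries were scaled with TMM factors, and a model with 1 mean per group was fitted over all 16 libraries (10 residual degrees of freedom), since 2 groups hold 2 libraries each. The square root of the common dispersion was 0.276. Each of 7 comparisons was tested with the quasi-likelihood F test of edgeR 4.0.16 under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. SEs are the absolute log2 fold change divided by the square root of F. Beside the median of a gene list, SE is the median of its genes' SEs, not an error of that median. CPM use TMM-scaled library sizes.

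Genes named by rule were the up to 12 higher and 12 lower with the largest fold changes among those called, whose groups did not overlap and whose mean over all libraries was at least 5 CPM, leaving out receptor segments and unnamed models. Members of the gene lists and 16 fixed genes, Foxp3 and Apoe among them, could be named as well. The 27 lists, fixed before the data were examined, cover T cell programmes (Treg, Th1, Th2, Th17, Tfh, naive and recirculating, effector memory, early T cell receptor, anergy and inhibitory receptor, proliferation), interferon response and metabolism (cholesterol synthesis, cholesterol efflux, glycolysis, respiratory chain, ribosomal protein). They also cover dissociation and stress, other cells (B, plasma, myeloid, dendritic, NK and cytotoxic, gamma-delta and innate-like, erythroid, stromal), Apoe neighbours and sex-linked genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Genes with no count in 1 group are given as bounds against a floor of 3 counts over the group.

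The edgeR test was tested on simulated data with the group sizes and spread of these libraries. For ApoB+ against ApoB-neg cells it called 72 of 100 genes changed 2-fold and 87 of 100 changed 4-fold, with 6 unchanged genes among 171 calls. For Apoe-/- against WT it called 63 of 100 and 89 of 100, with 11 unchanged genes among 166 calls. Alternatives were RLE and upper-quartile factors, no filter, a stricter filter (mean CPM of at least 5), edgeR with robust estimation, limma-voom, DESeq2 1.42.0, only the 2 groups compared, a block by replicate number, leaving out each replicate, the estimated correlation, an offset for transcript length and the lists without the sort genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and figures. No library was left out.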

Results

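The messenger RNA of CD4+ T cells sorted from mouse peripheral lymph nodes was counted per gene in 16 libraries of 6 groups. ApoB+ cells are CD4+ T cells that bound an MHC class II tetramer loaded with a peptide of the lipoprotein component apolipoprotein B, and ApoB-neg cells are CD4+ T cells that did not bind it. The ApoB+ groups came from Apoe-/- mice, which lack apolipoprotein E, of 4 weeks (n = 2), 8 weeks (n = 3) and 20 weeks (n = 3), and from wild-type (WT) mice of 8 weeks (n = 2). ApoB-neg cells (n = 3) and regulatory T cells (Tregs, n = 3) came from Apoe-/- mice of 8 weeks. Tregs were sorted as folate receptor 4-positive and CD25-positive cells within the tetramer-negative population, so Folr4 and Il2ra, the genes of those sort markers, carry no finding between Tregs and other groups. The labels do not say whether such cells were also taken out of the ApoB-neg cells. The total count per library ran from 34926158 to 45786417 in 8-week ApoB+ cells, 24581611 to 27012134 at 20 weeks, 32641047 to 32753369 at 4 weeks, 28329292 to 30987812 in WT ApoB+ cells, 27905866 to 42034123 in ApoB-neg cells and 20476092 to 39796652 in Tregs.

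Apoe (chromosome 7, 19696109 to 19699188), the gene knocked out, came to 3.6 ± 0.76 CPM (counts scaled to library size, mean ± SD, n = 2) in WT ApoB+ cells. In Apoe-/- ApoB+ cells it came to 2.57 ± 0.0516 CPM (n = 2) at 4 weeks, 1.93 ± 0.817 (n = 3) at 8 weeks and 0.844 ± 0.517 (n = 3) at 20 weeks. It came to 2.4 ± 0.397 (n = 3) in ApoB-neg cells and 2.19 ± 0.13 (n = 3) in Tregs. The counts cover the whole gene, and the part that the knockout removes is not given in the sources used here, so this level checks no label. Of the 13328 genes tested, the first principal component (23.8% of the variance) set the 3 Treg libraries apart from all others. The labels do not say that replicates are separate animals, and lymph nodes were pooled, so p-values measure only the spread between samples. Counts are of reads without molecular identifiers, so floors and intervals cover counting error only.

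Changes are log2 fold changes of the first-named group over the second, ± SE, with adjusted p from edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 13328 genes. Rose, fell, higher and lower are used for genes past 0.05 in that test, and locations (GRCm38 chromosome, start, end) follow a gene's first mention. The camera test sets each gene list against all other genes with a preset correlation between genes. With an estimated correlation, 26 list calls held. These were 11 of 13 for ApoB+ against ApoB-neg cells, 8 of 14 for ApoB+ cells against Tregs, 2 of 11 for Tregs against ApoB-neg cells, 1 of 12 for Apoe-/- against WT, and 2 of 11, 0 of 6 and 2 of 11 for 20 against 8, 8 against 4 and 20 against 4 weeks.

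ApoB+ against ApoB-neg cells of 8-week Apoe-/- mice asked how T cells that bind the tetramer differ from those that do not. If the sort took Tregs out of the ApoB-neg cells, Treg genes would be higher in ApoB+ cells for that reason alone. In ApoB+ cells 259 genes rose and 34 fell. Foxp3 (chromosome X, 7573644 to 7595245), which encodes the transcription factor that defines Tregs, rose by 2.19 ± 0.18 (adjusted p = 3.62e-05), from 50.3 ± 7.19 to 230.2 ± 20.1 CPM (SD, n = 3). The cytotoxic granule protease gene Gzmb (chromosome 14, 56258838 to 56262260) rose by 3.07 ± 0.47 (adjusted p = 0.00232), from 13.7 ± 5.19 to 115 ± 37 CPM (SD, n = 3), and Klrg1 (chromosome 6, 122270596 to 122282882), a receptor of terminally differentiated T cells, by 2.95 ± 0.32. Rorc (chromosome 3, 94372794 to 94398276), which encodes the Th17 transcription factor, rose by 2.21 ± 0.37 (adjusted p = 0.00384). Among the largest rises of the genes named by rule (mean of at least 5 CPM over all 16 libraries, groups that do not overlap) were the lectin gene Cd209b (chromosome 8, 3917655 to 3926844) (3.59 ± 0.44), the leukotriene receptor Ltb4r1 (chromosome 14, 55765962 to 55768494) (3.28 ± 0.54) and the chemokine receptor Ccr3 (chromosome 9, 124021972 to 124031689) (3.09 ± 0.50). The interferon-inducible GTPase Gbp1 (chromosome 3, 142594847 to 142619179) (2.98 ± 0.34) and the myosin gene Myo3b (chromosome 2, 70039126 to 70429198) (2.71 ± 0.33) rose too. The largest fall among genes named by that rule was in Ampd1 (chromosome 3, 103074014 to 103099720), an AMP deaminase gene, from 21.9 ± 1.36 to 8.29 ± 0.0596 CPM (SD, n = 3). Without 1 library the count of 293 genes became 135, 141 and 129 (8-week ApoB+ replicates 1, 2 and 3), and 129, 298 and 146 (ApoB-neg replicates 1, 2 and 3).

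Treg and effector genes were among those that rose. Of the 27 Treg genes, 20 were higher and 0 lower (24 and 0 adjusted over the list alone). The Treg list had a median of 1.15 and a camera adjusted p of 3.32e-65. They included Il2rb (chromosome 15, 78479256 to 78495271) (1.31 ± 0.12), an interleukin 2 receptor chain, Lrrc32 (chromosome 7, 98489283 to 98502181) (2.78 ± 0.29), which holds latent TGF-beta at the surface, and Ctla4 (chromosome 1, 60887000 to 60915832) (1.20 ± 0.15), an inhibitory receptor. Among 21 effector memory genes, 13 were higher and 0 lower (18 and 0 adjusted over the list alone). For the effector memory list camera gave an adjusted p of 1.59e-33 at a median of 1.06. Ccr2 (chromosome 9, 124101950 to 124113557) was at 2.27 ± 0.23, S100a4 (chromosome 3, 90603771 to 90606045) at 1.59 ± 0.25 and Cd44 (chromosome 2, 102811141 to 102901665) at 0.88 ± 0.12. The Th1 genes had 7 higher and 0 lower of 18 (13 and 0 adjusted over the list alone). The Th1 list had a median of 0.95 and a camera adjusted p of 1.65e-13. They included Nkg7 (chromosome 7, 43437073 to 43438249) (1.45 ± 0.21) and the chemokine receptor Ccr5 (chromosome 9, 124121543 to 124147699) (1.88 ± 0.33). Of the 15 Th17 genes, 7 were higher and 0 lower (11 and 0 adjusted over the list alone). For the Th17 list camera gave an adjusted p of 3.33e-18 at a median of 1.80. Besides Rorc, Rora (chromosome 9, 68653786 to 69388246) was at 1.31 ± 0.18 and Ccr6 (chromosome 17, 8236043 to 8257141) at 1.80 ± 0.30. Among 16 follicular helper (Tfh) genes, 5 were higher and 0 lower (7 and 0 adjusted over the list alone). The Tfh list had a median of 0.49 and a camera adjusted p of 3.43e-06. The Th2 genes had 1 higher and 0 lower of 12 (5 and 1 adjusted over the list alone). For the Th2 list camera gave an adjusted p of 0.00263 (adjusted p = 0.0841 with an estimated correlation) at a median of 0.86. The 1 called was Ccr8 (chromosome 9, 120092114 to 120094906) (1.15 ± 0.18).

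Some genes of DNA synthesis and mitosis rose as well. Of the 25 proliferation genes, 11 were higher and 0 lower (22 and 0 adjusted over the list alone). The proliferation list had a median of 1.04 and a camera adjusted p of 1.57e-21. Top2a (chromosome 11, 98992943 to 99024189) was at 1.09 ± 0.18 and Rrm2 (chromosome 12, 24708241 to 24714146) at 1.22 ± 0.21. Among 20 anergy and inhibitory receptor genes, 6 were higher and 0 lower (10 and 1 adjusted over the list alone). Ctla4, Tigit, Entpd1, Nt5e and Nrp1, all higher here, are on the Treg list too, so the calls of these lists overlap. For the anergy list camera gave an adjusted p of 9.7e-13 at a median of 0.49. The ectoenzymes Entpd1 (chromosome 19, 40612366 to 40741602) and Nt5e (chromosome 9, 88327197 to 88372092), which make adenosine, were at 1.88 ± 0.26 and 1.03 ± 0.15. The naive and recirculating T cell genes had 0 higher and 3 lower of 18 (0 and 9 adjusted over the list alone). The naive list had a median of -0.44 and a camera adjusted p of 1e-09. The lymph node homing receptor gene Sell (chromosome 1, 164061982 to 164084181) was at -0.56 ± 0.14 and did not pass (adjusted p = 0.0558, or 0.0473 with upper-quartile factors, 0.0344 with no filter, 0.029 with a stricter filter, 0.0349 with a length offset, 0.00549 with only the 2 groups, 0.0285 with limma-voom and 0.0077 with DESeq2). Of the 40 ribosomal protein genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone). For the ribosomal list camera gave an adjusted p of 4.08e-05 (adjusted p = 0.531 with an estimated correlation) at a median of -0.17. Among 24 interferon response genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone). The interferon list did not pass camera (median 0.06, adjusted p 0.938, or 0.0422 without 8-week ApoB+ replicate 3). The test pointed lower, unlike the median and mean. Apoe itself did not pass (-0.31 ± 0.47).

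Markers of other cells moved with these T cell genes, although the sort excluded cells with CD11b, CD11c, F4/80, CD8, CD19, Nk1.1 and Ter-119. The macrophage lysozyme gene Lyz2 (chromosome 10, 117277331 to 117282321) stood at 26 CPM in 8-week, 26.3 in 4-week and 28.4 in 20-week ApoB+ cells of Apoe-/- mice, against 5.72 in ApoB-neg cells, 6.03 in WT ApoB+ cells and 1.64 in Tregs. The MHC class II gene H2-Ab1 (chromosome 17, 34257689 to 34269419) rose by 3.78 ± 0.54 (adjusted p = 0.00153), from 0.882 ± 0.413 to 12 ± 6.1 CPM (SD, n = 3). The myeloid cell markers had 3 higher and 0 lower of 20 (10 and 0 adjusted over the list alone). For the myeloid list camera gave an adjusted p of 1.8e-06 at a median of 1.51. Of the 14 B cell markers, 6 were higher and 0 lower (7 and 0 adjusted over the list alone). The B list had a median of 1.68 and a camera adjusted p of 5.78e-10. The class II genes on that list are expressed by other antigen-presenting cells too. Among 10 gamma-delta and innate-like T cell markers, 3 were higher and 0 lower (5 and 0 adjusted over the list alone). For the gamma-delta list camera gave an adjusted p of 0.000296 at a median of 0.86. Rorc and Tmem176b (chromosome 6, 48833818 to 48841496) (1.19 ± 0.20) are Th17 genes too. The dendritic cell markers had 1 higher and 0 lower of 11 (1 and 0 adjusted over the list alone). The dendritic list did not pass camera (median 0.71, adjusted p 0.102, or 0.0401 without ApoB-neg replicate 3, 0.00752 with a stricter filter). Of the 15 NK and cytotoxic lymphocyte markers, 3 were higher and 0 lower (3 and 1 adjusted over the list alone). By camera the NK list did not pass (median 0.54, adjusted p 0.0839, or 0.00829 without 8-week ApoB+ replicate 2 and 0.0475 without ApoB-neg replicate 3, 0.0226 with a stricter filter and 0.0371 with a length offset).

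**Figure D1:**
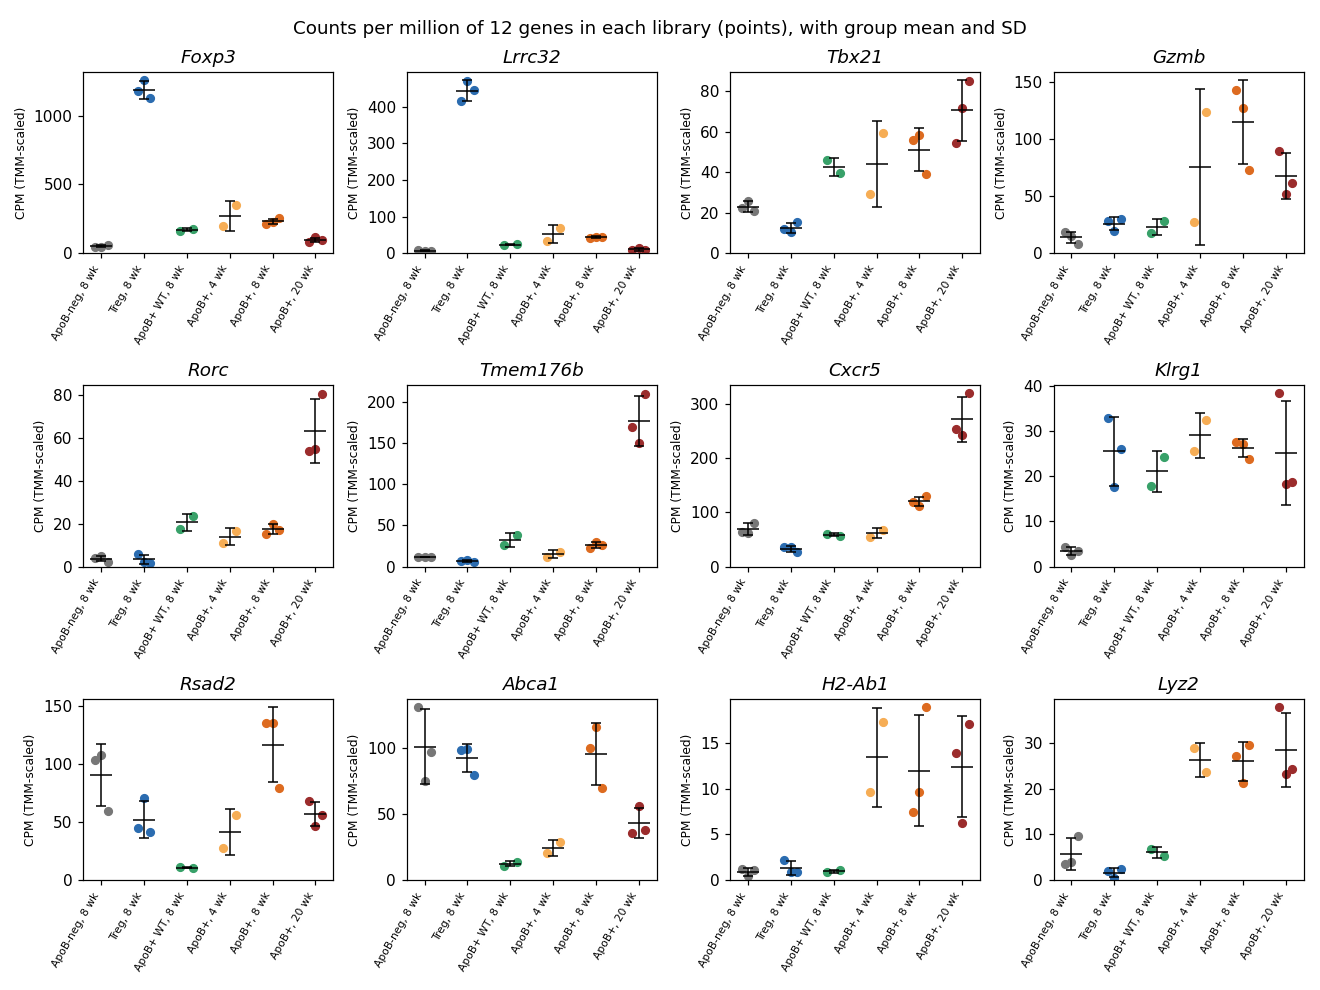
CPM of 12 genes, 1 panel each, in every library (points) with the group mean and SD, for ApoB-neg cells, Tregs and the 4 ApoB+ groups. Mean Lyz2 was 26.0 CPM in 8-week Apoe-/- ApoB+ cells and 6.03 CPM in WT ApoB+ cells, and mean Foxp3 was above the ApoB-neg level (50.3 CPM) in all 4 ApoB+ groups.

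ApoB+ cells against sorted Tregs of the same age and genotype asked how ApoB+ cells differ from Tregs of other specificity. In ApoB+ cells 1081 genes rose and 700 fell. Foxp3 was lower by 2.37 ± 0.18 on the log2 scale (adjusted p = 2.65e-07), at 230.2 ± 20.1 against 1188 ± 64.8 CPM (SD, n = 3). By the same rule the largest falls included the glutathione transferase Gsta4 (chromosome 9, 78182774 to 78209349) (-4.77 ± 0.32), the receptor Gpr83 (chromosome 9, 14860210 to 14870789) (-3.53 ± 0.19), the matrix protein Ecm1 (chromosome 3, 95734147 to 95739569) (-3.45 ± 0.16) and Lrrc32 (-3.35 ± 0.28). Cd209b and the purine receptor P2ry1 (chromosome 3, 61002795 to 61008982) had no count in the 3 Treg libraries and were at least 567-fold and 456-fold higher in ApoB+ cells, against a floor of 3 counts over the group. The LIM-domain gene Pdlim4 (chromosome 11, 54054928 to 54069014) rose by 7.39 ± 0.36, from 0.244 ± 0.228 to 48.3 ± 6.25 CPM (SD, n = 3), and the calcium channel gene Ryr1 (chromosome 7, 29003344 to 29125179) by 6.36 ± 0.53. Without 8-week ApoB+ replicate 1 the count of 1781 genes was 1104, and without Treg replicate 1 it was 1171.

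Most Treg genes called were lower and most helper genes called higher in ApoB+ cells than in Tregs. Among 27 Treg genes, 1 were higher and 19 lower (2 and 21 adjusted over the list alone). The Treg list had a median of -1.28 and a camera adjusted p of 1.17e-40. In a test chosen after the values were seen, the Treg list without the sort genes Folr4 and Il2ra had 1 higher and 17 lower of 25 (camera adjusted p 1.37e-35). Ikzf4 (chromosome 10, 128630843 to 128645991), a Treg transcription factor gene, was at -2.76 ± 0.23, Swap70 (chromosome 7, 110221711 to 110283506) at -2.55 ± 0.15 and Tnfrsf18 (chromosome 4, 156026164 to 156028895), which encodes GITR, at -1.68 ± 0.13. The Th1 genes had 13 higher and 1 lower of 18 (13 and 1 adjusted over the list alone). For the Th1 list camera gave an adjusted p of 1.47e-10 at a median of 1.80. Tbx21 (chromosome 11, 97098071 to 97115331), the Th1 transcription factor gene, was at 2.05 ± 0.25, Cxcr3 (chromosome X, 101731535 to 101734269) at 2.35 ± 0.26 and Ifng (chromosome 10, 118441046 to 118445892), the Th1 cytokine gene, at 2.57 ± 0.37. Of the 15 Th17 genes, 10 were higher and 0 lower (10 and 0 adjusted over the list alone). The Th17 list had a median of 2.06 and a camera adjusted p of 2.68e-08. Rorc was at 2.37 ± 0.37. Among 16 follicular helper (Tfh) genes, 11 were higher and 1 lower (12 and 2 adjusted over the list alone). For the Tfh list camera gave an adjusted p of 3.18e-08 at a median of 0.95. The follicle homing receptor gene Cxcr5 (chromosome 9, 44511787 to 44561877) was at 1.88 ± 0.16 and the transcription factor gene Tox2 (chromosome 2, 163203125 to 163324170) at 2.87 ± 0.28. The effector memory genes had 14 higher and 0 lower of 21 (16 and 0 adjusted over the list alone). The effector memory list had a median of 1.67 and a camera adjusted p of 1.11e-26. The transcription regulator Id2 (chromosome 12, 25093799 to 25097140) was at 3.18 ± 0.17 and the chemokine receptor Cxcr6 (chromosome 9, 123806475 to 123811760) at 4.60 ± 0.38.

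Most cytotoxic, innate-like and cycling cell genes tested were higher in ApoB+ cells. Of the 15 NK and cytotoxic lymphocyte markers, 9 were higher and 0 lower (9 and 0 adjusted over the list alone). For the NK list camera gave an adjusted p of 3.34e-09 at a median of 2.59 (2.15 with genes at 0 in 1 group set to their bound). The NK receptor gene Klrd1 (chromosome 6, 129591782 to 129598775) was at 4.82 ± 0.45. Among 10 gamma-delta and innate-like T cell markers, 6 were higher and 0 lower (6 and 0 adjusted over the list alone). The gamma-delta list had a median of 4.49 (2.63 with genes at 0 in 1 group set to their bound) and a camera adjusted p of 1.5e-07. Zbtb16 (chromosome 9, 48654297 to 48836222), a transcription factor gene of innate-like T cells, was at least 101-fold higher. The proliferation genes had 14 higher and 0 lower of 25 (19 and 0 adjusted over the list alone). For the proliferation list camera gave an adjusted p of 1.9e-10 (adjusted p = 0.133 with an estimated correlation) at a median of 1.15. The cycling cell marker Mki67 (chromosome 7, 135689784 to 135716361) was at 1.69 ± 0.25. Myeloid markers moved with these groups. Of the 20 myeloid cell markers, 11 were higher and 2 lower (12 and 2 adjusted over the list alone). The myeloid list had a median of 3.96 (3.80 with genes at 0 in 1 group set to their bound) and a camera adjusted p of 1.51e-05 (adjusted p = 0.56 with a stricter filter). Lyz2 was at 3.93 ± 0.45.

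Other lists covered protein synthesis, energy and further T cell states. Among 40 ribosomal protein genes, 0 were higher and 23 lower (0 and 39 adjusted over the list alone). For the ribosomal list camera gave an adjusted p of 3.7e-12 (adjusted p = 0.33 with an estimated correlation) at a median of -0.54. The nuclear respiratory chain genes had 0 higher and 2 lower of 32 (0 and 11 adjusted over the list alone). The respiratory list had a median of -0.36 and a camera adjusted p of 7.04e-06 (adjusted p = 0.508 with an estimated correlation, 0.09 with a length offset). With an offset for transcript length, chosen after the results were seen, these medians were -0.33 (ribosomal) and -0.12 (respiratory). Of the 12 Th2 genes, 3 were higher and 0 lower (3 and 0 adjusted over the list alone). For the Th2 list camera gave an adjusted p of 0.0283 (adjusted p = 0.24 with an estimated correlation, 0.0697 without 8-week ApoB+ replicate 2 and 0.0559 without Treg replicate 2, 0.0613 with no filter, 0.611 with a stricter filter, 0.0901 with only the 2 groups, 0.331 with limma-voom and 0.0787 with DESeq2) at a median of 1.73 (1.46 with genes at 0 in 1 group set to their bound). Among 20 early genes induced by the T cell receptor, 1 were higher and 6 lower (1 and 7 adjusted over the list alone). The early list had a median of -0.26 and a camera adjusted p of 0.0151 (adjusted p = 0.312 with an estimated correlation, 0.0871 without 8-week ApoB+ replicate 1). The naive and recirculating T cell genes had 6 higher and 2 lower of 18 (6 and 2 adjusted over the list alone). By camera the naive list did not pass (median 0.06, adjusted p 0.0901, or 0.0172 without 8-week ApoB+ replicate 3). The survival receptor gene Il7r (chromosome 15, 9505788 to 9530176) was higher by 1.63 ± 0.15 and Tcf7 (chromosome 11, 52252371 to 52283014) by 1.24 ± 0.12. Of the 20 anergy and inhibitory receptor genes, 4 were higher and 5 lower (4 and 5 adjusted over the list alone). The anergy list did not pass camera (median -0.03, adjusted p 0.0786, or 0.0271 without 8-week ApoB+ replicate 3 and 0.0411 without Treg replicate 1). Apoe did not pass (-0.18 ± 0.47, or 0.13 without 8-week ApoB+ replicate 2).

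Tregs against ApoB-neg cells gave the profile of sorted Tregs at the same age and genotype. Here 803 genes rose and 825 fell in Tregs. Foxp3 rose by 4.56 ± 0.20 (adjusted p = 1.49e-09), from 50.3 ± 7.19 to 1188 ± 64.8 CPM (SD, n = 3), and Lrrc32 by 6.12 ± 0.33, from 6.39 ± 2.07 to 445 ± 27.8 CPM (SD, n = 3). The cytokine signal inhibitor Socs2 (chromosome 10, 95385362 to 95417180) rose by 4.23 ± 0.29 and Gpr83 by 4.11 ± 0.20. P2ry1 was at least 215-fold lower, with no count in Tregs, and Pdlim4 fell by 8.29 ± 0.37 on the log2 scale. Among 27 Treg genes, 24 were higher and 0 lower (25 and 0 adjusted over the list alone). For the Treg list camera gave an adjusted p of 4.75e-111 at a median of 2.70. The anergy and inhibitory receptor genes had 8 higher and 2 lower of 20 (10 and 2 adjusted over the list alone). The anergy list had a median of 0.45 and a camera adjusted p of 2.32e-09. These lists hold the sort genes Folr4 and Il2ra, and in a test chosen after the values were seen the Treg list without them had 22 of 25 genes higher (camera adjusted p 8.98e-100) and the anergy list 7 higher and 2 lower of 19 (4.22e-07). Entpd1 and Ctla4, which are on both lists, were at 3.01 ± 0.27 and 2.13 ± 0.15. Apoe did not pass (-0.13 ± 0.47, or 0.01 without ApoB-neg replicate 1).

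Genes of recirculation and memory differed between Tregs and ApoB-neg cells, in both directions for memory. Of the 18 naive and recirculating T cell genes, 0 were higher and 8 lower (0 and 10 adjusted over the list alone). For the naive list camera gave an adjusted p of 1e-07 (adjusted p = 0.0959 with an estimated correlation) at a median of -0.37. Il7r was at -1.76 ± 0.15 and Tcf7 at -1.46 ± 0.12. Among 21 effector memory genes, 4 were higher and 8 lower (4 and 9 adjusted over the list alone). The effector memory list had a median of -0.26 and a camera adjusted p of 0.00133 (adjusted p = 0.487 with an estimated correlation, 0.059 without Treg replicate 2). Id2 was at -2.50 ± 0.16 and Cxcr6 at -3.47 ± 0.36, while Klrg1 rose by 2.91 ± 0.32. The NK and cytotoxic lymphocyte markers had 0 higher and 6 lower of 15 (0 and 7 adjusted over the list alone). For the NK list camera gave an adjusted p of 4.72e-06 (adjusted p = 0.0676 with an estimated correlation) at a median of -2.28 (-2.05 with genes at 0 in 1 group set to their bound). Of the 10 gamma-delta and innate-like T cell markers, 0 were higher and 4 lower (0 and 4 adjusted over the list alone). The gamma-delta list had a median of -2.44 (-1.79 with genes at 0 in 1 group set to their bound). Camera gave an adjusted p of 0.00568 (0.0676 with an estimated correlation). Among 14 B cell markers, 4 were higher and 1 lower (4 and 1 adjusted over the list alone). For the B list camera gave an adjusted p of 0.00133 (adjusted p = 0.125 with an estimated correlation) at a median of 1.70. Cd79b (chromosome 11, 106311341 to 106314762), a B cell receptor chain gene, was at 3.20 ± 0.23. The follicular helper (Tfh) genes had 2 higher and 6 lower of 16 (2 and 8 adjusted over the list alone). The Tfh list had a median of -0.40 and a camera adjusted p of 0.0144 (adjusted p = 0.165 with an estimated correlation, 0.0541 without Treg replicate 2, 0.0687 with a stricter filter). Of the 20 early genes induced by the T cell receptor, 8 were higher and 1 lower (9 and 2 adjusted over the list alone). For the early list camera gave an adjusted p of 0.00134 (adjusted p = 0.244 with an estimated correlation) at a median of 0.42. Among 32 nuclear respiratory chain genes, 6 were higher and 0 lower (13 and 0 adjusted over the list alone). The respiratory list had a median of 0.38 and a camera adjusted p of 1.67e-05 (adjusted p = 0.563 with an estimated correlation). The ribosomal protein genes had 5 higher and 0 lower of 40 (8 and 0 adjusted over the list alone). For the ribosomal list camera gave an adjusted p of 3.83e-05 (adjusted p = 0.641 with an estimated correlation, 0.051 without Treg replicate 1) at a median of 0.37. With an offset for transcript length the medians were 0.13 for the respiratory and 0.21 for the ribosomal list.

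ApoB+ cells shared part of the Treg profile. Of the 259 genes higher in ApoB+ than in ApoB-neg cells, 115 were also higher in Tregs, 24 were lower in Tregs, and 124 were also higher in ApoB+ cells than in Tregs. Foxp3 lay between, at 50.3, 230.2 and 1188 CPM in ApoB-neg cells, ApoB+ cells and Tregs. Gzmb did not, at 13.7, 115 and 25.9 CPM, nor did Rorc, at 3.72, 17.4 and 3.31 CPM. The 2 comparisons use the same 3 ApoB-neg libraries. In the same direction 128 genes were called in both (115 higher, 13 lower), against 15.6 and 2.1 expected of independent lists. Across genes, which are not independent replicates, the correlation of the fold changes was 0.341, against 0.503 in 20 simulations of unchanged groups with these controls, and the covariance 0.526 against 0.27. Among the 9378 genes of mean CPM 5 or more the correlation was 0.281 against 0.501 and the covariance 0.0742 against 0.0251. The controls were not split, and a shift of ApoB-neg cells would also raise the covariance, so shared controls may give part of the excess overlap. The overlap was 68, 73 and 63 without 8-week ApoB+ replicates 1, 2 and 3, and 73 and 65 without ApoB-neg replicates 1 and 3.

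ApoB+ cells of Apoe-/- against WT mice at 8 weeks asked what the knockout, which raises plasma cholesterol, does to these cells. In Apoe-/- cells 864 genes rose and 552 fell. Apoe itself changed by -0.90 ± 0.51 and did not pass (adjusted p = 0.27). The antiviral gene Rsad2 (chromosome 12, 26442746 to 26456452) rose by 3.45 ± 0.38 (adjusted p = 0.00018), from 10.6 ± 0.45 (SD, n = 2) to 116 ± 32.4 CPM (SD, n = 3). Abca1 (chromosome 4, 53030787 to 53159895), which encodes the cholesterol exporter induced by the sterol sensor LXR, rose by 2.94 ± 0.30 (adjusted p = 9.34e-05), from 12.4 ± 2.06 (SD, n = 2) to 95 ± 23.4 CPM (SD, n = 3). The amino acid transporter Slc1a5 (chromosome 7, 16781340 to 16798274) fell by 1.79 ± 0.17 on the log2 scale (adjusted p = 9.34e-05), from 314 ± 40.3 (SD, n = 2) to 90.8 ± 14.6 CPM (SD, n = 3), and the brain creatine kinase Ckb (chromosome 12, 111669361 to 111672338) by 1.17 ± 0.17. Without 1 library the count of 1416 genes became 443, 562 and 600 (8-week ApoB+ replicates 1, 2 and 3), and 115 and 644 (WT replicates 1 and 2). With upper-quartile factors 724 genes were higher and 877 lower.

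Interferon response genes were higher in Apoe-/- cells. Of the 24 interferon response genes, 24 were higher and 0 lower (24 and 0 adjusted over the list alone). The interferon list had a median of 1.76 and a camera adjusted p of 1.86e-36 (adjusted p = 0.0669 with an estimated correlation). Besides Rsad2, the antiviral genes Ifi44 (chromosome 3, 151730922 to 151749960) (3.10 ± 0.48), Mx1 (chromosome 16, 97447035 to 97462907) (2.91 ± 0.41) and Ifit3 (chromosome 19, 34583531 to 34588731) (2.89 ± 0.38) had the largest changes of the list, and the interferon signal transducer Stat1 (chromosome 1, 52119440 to 52161865) rose by 1.08 ± 0.11. The mean log2 CPM of this list was 5.32 in each WT library and 6.76 to 7.46 in the 8-week Apoe-/- ApoB+ libraries. Genes of cholesterol handling went both ways. Among 14 cholesterol efflux and LXR target genes, 5 were higher and 1 lower (6 and 2 adjusted over the list alone). By camera the cholesterol efflux list did not pass (median 0.37, adjusted p 0.0537, or 0.0131 without 8-week ApoB+ replicate 3, 0.0487 with RLE factors, 0.033 with only the 2 groups and 0.0309 with DESeq2). The cholesterol synthesis and uptake genes had 1 higher and 4 lower of 24 (1 and 7 adjusted over the list alone). The cholesterol synthesis list had a median of -0.31 and a camera adjusted p of 0.000145.

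T cell lists differed as well. Of the 27 Treg genes, 5 were higher and 0 lower (8 and 0 adjusted over the list alone). For the Treg list camera gave an adjusted p of 0.00153 (adjusted p = 0.322 with an estimated correlation) at a median of 0.44. Nrp1 (chromosome 8, 128358604 to 128503363) was at 0.93 ± 0.14 and Swap70 at 1.07 ± 0.17. Foxp3 did not pass (0.44 ± 0.20, adjusted p = 0.165, or 0.0205 with only the 2 groups compared). Among 18 Th1 genes, 4 were higher and 0 lower (6 and 1 adjusted over the list alone). The Th1 list had a median of 0.29 and a camera adjusted p of 0.0136 (adjusted p = 0.322 with an estimated correlation, 0.134 without WT ApoB+ replicate 1). The follicular helper (Tfh) genes had 4 higher and 0 lower of 16 (4 and 0 adjusted over the list alone). For the Tfh list camera gave an adjusted p of 0.0119 (adjusted p = 0.228 with an estimated correlation, 0.0591 without WT ApoB+ replicate 1) at a median of 0.34. Pdcd1 (chromosome 1, 94038305 to 94052553), which encodes PD-1, was at 1.06 ± 0.14 and Cxcr5 at 1.04 ± 0.18. Of the 18 naive and recirculating T cell genes, 0 were higher and 6 lower (0 and 7 adjusted over the list alone). The naive list had a median of -0.26 and a camera adjusted p of 0.000458 (adjusted p = 0.234 with an estimated correlation). Among 20 anergy and inhibitory receptor genes, 4 were higher and 0 lower (5 and 0 adjusted over the list alone). For the anergy list camera gave an adjusted p of 0.00153 (adjusted p = 0.193 with an estimated correlation) at a median of 0.33. The early genes induced by the T cell receptor had 2 higher and 0 lower of 20 (2 and 0 adjusted over the list alone). The early list had a median of 0.40 and a camera adjusted p of 0.031 (adjusted p = 0.333 with an estimated correlation, 0.0761 without 8-week ApoB+ replicate 2, 0.0743 without 8-week ApoB+ replicate 3 and 0.101 without WT ApoB+ replicate 2, 0.077 with a stricter filter). Of the 25 proliferation genes, 2 were higher and 0 lower (5 and 0 adjusted over the list alone). For the proliferation list camera gave an adjusted p of 0.0352 (adjusted p = 0.633 with an estimated correlation, 0.075 without 8-week ApoB+ replicate 1 and 0.528 without WT ApoB+ replicate 1, 0.0522 with a stricter filter and 0.0759 with a length offset) at a median of 0.29. The hypoxia regulator Hif1a (chromosome 12, 73901375 to 73947530) rose by 1.08 ± 0.12. Markers of myeloid cells moved with the interferon genes, with Lyz2 at 6.03 CPM in WT and 26 in Apoe-/- cells. Among 20 myeloid cell markers, 2 were higher and 0 lower (2 and 0 adjusted over the list alone). The myeloid list had a median of 1.04 and a camera adjusted p of 0.0472 (adjusted p = 0.234 with an estimated correlation, 0.0612 without 8-week ApoB+ replicate 1, 0.059 without 8-week ApoB+ replicate 3 and 0.151 without WT ApoB+ replicate 2, 0.0897 with a stricter filter and 0.0592 with only the 2 groups).

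Short transcripts made up most of the falls. The nuclear respiratory chain genes had 0 higher and 18 lower of 32 (0 and 32 adjusted over the list alone). For the respiratory list camera gave an adjusted p of 1.09e-16 (adjusted p = 0.234 with an estimated correlation) at a median of -0.58. Of the 40 ribosomal protein genes, 0 were higher and 5 lower (0 and 27 adjusted over the list alone). The ribosomal list had a median of -0.49 and a camera adjusted p of 1.78e-12 (adjusted p = 0.322 with an estimated correlation, 0.163 with a length offset). The median transcript was 4704 nt for genes called higher and 1357.5 nt for genes called lower, against 3002 nt for all. Fold change rose with length (rho = 0.416 across 13155 genes, which are not independent replicates). With an offset for transcript length, 658 genes were called, 481 of them among the 1416 called without it. With that offset 2 of the 72 genes of both lists were lower, with a median of -0.03.

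Genes near Apoe on chromosome 7 differed by 2-fold more often between the genotypes. In a window and at a fold chosen after the values were seen, 18 of 208 genes within 10 Mb of Apoe were called at 2-fold or more (8.65% against 3.02% elsewhere, two-sided Fisher exact test p = 8.78e-05 over genes). At any fold 31 of the 208 were called (14.9% against 10.6% elsewhere). Of the 18, 12 were higher and 6 lower in Apoe-/- cells, and 4 of those higher had no count in WT cells. They include Slc1a5, at 314 CPM in WT cells and 70.2 to 98 CPM in the 5 Apoe-/- groups, Pglyrp1 (chromosome 7, 18871331 to 18890459) (-2.07 ± 0.32) and, chosen after its values were seen, the F-box gene Fbxo17 (chromosome 7, 28716804 to 28738144) (1.76 ± 0.29). In ApoB+ against ApoB-neg cells, both Apoe-/-, 2 of the 208 were called at that size (Fisher p = 1). Among 40 Apoe neighbours on chromosome 7, 5 were higher and 4 lower (5 and 4 adjusted over the list alone). By camera the Apoe neighbour list did not pass (median -0.10, adjusted p 0.51). Their mean was 0.50 and the test pointed lower, so the signs of median and mean differ.

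**Figure D2:**
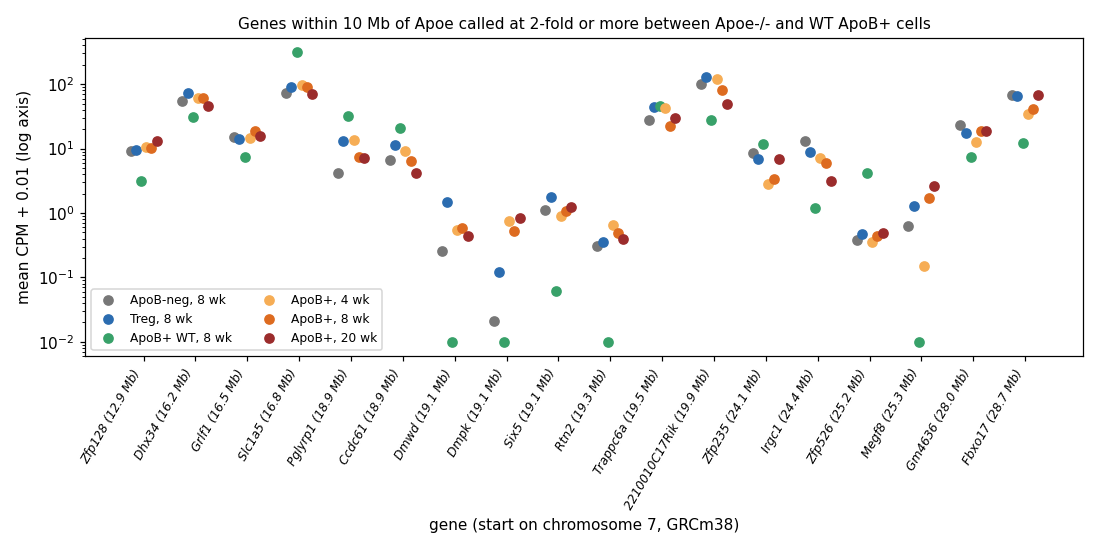
Mean CPM + 0.01 (log axis) in each of the 6 groups (points) of the 18 genes within 10 Mb of Apoe called at 2-fold or more between Apoe-/- and WT ApoB+ cells, in order of position on chromosome 7. Slc1a5 stands at 313.7 CPM in WT cells and at 70.2 to 98.0 CPM in the 5 Apoe-/- groups.

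ApoB+ cells of Apoe-/- mice at 20 against 8 weeks asked how these cells change with age, as disease proceeds in this strain. At 20 weeks 130 genes rose and 175 fell. Tmem176a (chromosome 6, 48840919 to 48847071) and Tmem176b, paired membrane protein genes of Th17 cells, rose by 3.27 ± 0.30 and 2.77 ± 0.21 (adjusted p = 4.08e-05 and 7.81e-06), Tmem176b from 25.8 ± 3.36 to 176 ± 30.4 CPM (SD, n = 3). Foxp3 fell by 1.26 ± 0.18 on the log2 scale (adjusted p = 0.00166), from 230.2 ± 20.1 to 95.9 ± 16.7 CPM (SD, n = 3), and Lrrc32 by 2.11 ± 0.28. Among genes named by rule the largest falls included the phosphatase Dusp4 (chromosome 8, 34807297 to 34819894) (-2.67 ± 0.37) and the RNA sensor Tlr7 (chromosome X, 167304929 to 167330558) (-1.82 ± 0.23), and the largest rises included Actn2 (chromosome 13, 12269426 to 12340760) (2.08 ± 0.34) and Anxa1 (chromosome 19, 20373428 to 20390944) (1.91 ± 0.26). Apoe did not pass (-1.18 ± 0.48). Without 1 library the count of 305 genes became 131, 1519 and 103 (20-week replicates 1, 2 and 3), and 102, 93 and 185 (8-week replicates 1, 2 and 3). With upper-quartile factors 190 genes were higher and 159 lower. The median transcript was 2010 nt for genes called higher and 4064 nt for genes called lower (rho of fold change with length = -0.285 across genes), and with an offset for transcript length the ribosomal list passed camera (adjusted p 2.23e-06).

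With age some Th17 genes rose, while some Treg and naive cell genes fell. The Th17 genes had 6 higher and 0 lower of 15 (12 and 1 adjusted over the list alone). The Th17 list had a median of 2.25 and a camera adjusted p of 4.91e-19. The chemokine receptor gene Ccr6 was at 1.75 ± 0.30. Of the 10 gamma-delta and innate-like T cell markers, 2 were higher and 0 lower (3 and 1 adjusted over the list alone). The gamma-delta list, with Th17 genes, had a median of 1.04 (camera adjusted p 7.94e-05). Among 27 Treg genes, 0 were higher and 7 lower (4 and 9 adjusted over the list alone). The Treg list had a median of -0.21 and a camera adjusted p of 7.29e-06 (adjusted p = 0.194 with an estimated correlation). Swap70 was at -1.67 ± 0.15 and Gata1 (chromosome X, 7959260 to 7978071) at -1.86 ± 0.25. The naive and recirculating T cell genes had 1 higher and 10 lower of 18 (1 and 12 adjusted over the list alone). For the naive list camera gave an adjusted p of 6.03e-10 (adjusted p = 0.0625 with an estimated correlation) at a median of -0.60. Sell was at -0.94 ± 0.15 and Bach2 (chromosome 4, 32238804 to 32586108), a repressor of effector genes, at -1.20 ± 0.18. Of the 21 effector memory genes, 5 were higher and 0 lower (10 and 0 adjusted over the list alone). The effector memory list had a median of 0.42 and a camera adjusted p of 1.97e-09 (adjusted p = 0.136 with an estimated correlation). Id2 was at 1.05 ± 0.15. Among 16 follicular helper (Tfh) genes, 3 were higher and 0 lower (6 and 1 adjusted over the list alone). For the Tfh list camera gave an adjusted p of 0.000411 (adjusted p = 0.0625 with an estimated correlation) at a median of 0.37. Cxcr5 rose by 1.18 ± 0.15, from 119.9 ± 9.17 to 272 ± 41.5 CPM (SD, n = 3).

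Some interferon genes were lower at 20 than at 8 weeks. The interferon response genes had 0 higher and 7 lower of 24 (0 and 20 adjusted over the list alone). The interferon list had a median of -0.84 and a camera adjusted p of 4.3e-17 (adjusted p = 0.136 with an estimated correlation). Oas2 (chromosome 5, 120730333 to 120749853) was at -2.85 ± 0.39 and Mx2 (chromosome 16, 97535308 to 97560900) at -1.47 ± 0.24. Of the 14 cholesterol efflux and LXR target genes, 0 were higher and 3 lower (0 and 4 adjusted over the list alone). For the cholesterol efflux list camera gave an adjusted p of 0.0139 (adjusted p = 0.12 with an estimated correlation, 0.0764 without 20-week ApoB+ replicate 2, 0.0517 with a stricter filter, 0.0769 with a length offset and 0.0544 with DESeq2) at a median of -0.20. Among 20 early genes induced by the T cell receptor, 0 were higher and 2 lower (1 and 6 adjusted over the list alone). The early list had a median of -0.37 and a camera adjusted p of 0.000177 (adjusted p = 0.148 with an estimated correlation). Tnfrsf9 (chromosome 4, 150914562 to 150946102), which encodes 4-1BB, was at -0.95 ± 0.15. The Th1 genes had 0 higher and 1 lower of 18 (2 and 1 adjusted over the list alone). For the Th1 list camera gave an adjusted p of 0.0309 (adjusted p = 0.463 with an estimated correlation, 0.0537 without 20-week ApoB+ replicate 1, 0.0568 without 8-week ApoB+ replicate 2 and 0.0755 without 8-week ApoB+ replicate 3, 0.0557 with DESeq2) at a median of 0.30. Of the 21 dissociation and stress genes, 0 were higher and 0 lower (0 and 2 adjusted over the list alone). The dissociation list had a median of -0.41 and a camera adjusted p of 0.000827 (adjusted p = 0.394 with an estimated correlation). The myeloid marker Lyz2 did not move with these groups, at 26 and 28.4 CPM. Among 20 myeloid cell markers, 0 were higher and 0 lower (1 and 1 adjusted over the list alone). By camera the myeloid list did not pass (median 0.04, adjusted p 0.607). Their mean was -0.39 and the test pointed lower, so the signs of median and mean differ.

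**Figure D3:**
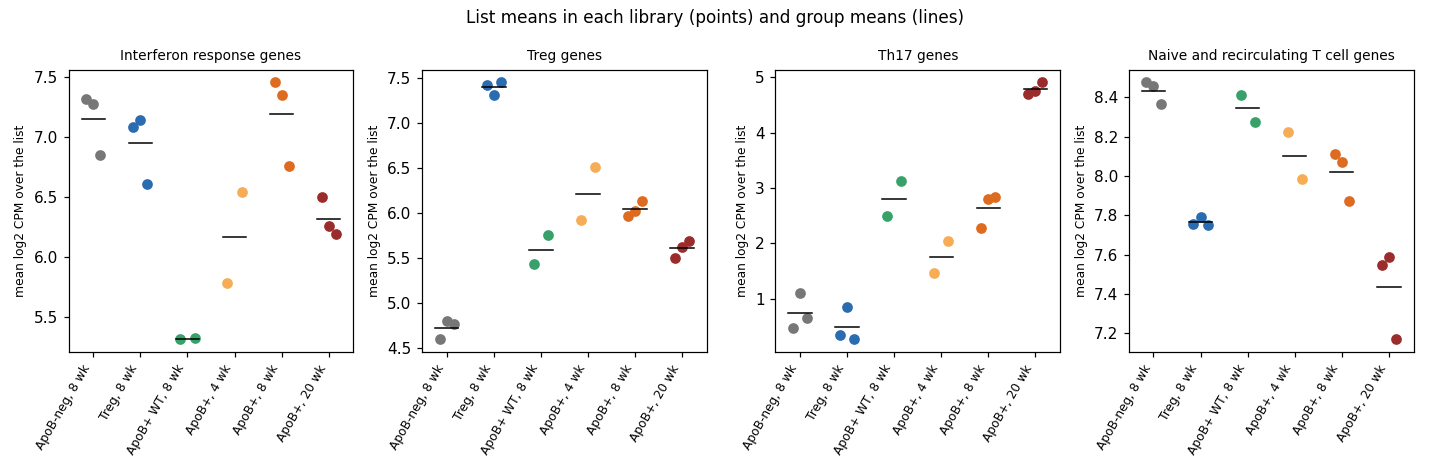
Mean log2 CPM over 4 gene lists, 1 panel each, in every library (points) with group means (lines). The interferon list stands at 5.32 in both WT libraries and at 6.61 to 7.46 in the 9 libraries of 8-week Apoe-/- mice, and the Th17 list is highest in the 3 libraries of 20 weeks.

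ApoB+ cells of Apoe-/- mice at 8 against 4 weeks covered the earlier interval. At 8 weeks 1010 genes rose and 1124 fell. Abca1 rose by 1.97 ± 0.28 (adjusted p = 0.00198), from 24.3 ± 5.96 (SD, n = 2) to 95 ± 23.4 CPM (SD, n = 3), and the drug exporter Abcb1a (chromosome 5, 8660077 to 8748575) by 2.62 ± 0.30 (adjusted p = 0.000679). The antiviral gene Mx2 rose by 2.03 ± 0.28 (adjusted p = 0.00178), from 5.21 ± 0.874 (SD, n = 2) to 21.3 ± 5.68 CPM (SD, n = 3). Itm2a (chromosome X, 107397099 to 107403376), a membrane protein gene of early T cell activation, fell by 1.48 ± 0.23 on the log2 scale, from 365 ± 131 (SD, n = 2) to 131 ± 4.83 CPM (SD, n = 3), and the relaxin gene Rln3 (chromosome 8, 84042929 to 84045000) by 1.98 ± 0.20. Apoe did not pass (-0.41 ± 0.52). Without 1 library the count of 2134 genes became 1184, 1236 and 1267 (8-week replicates 1, 2 and 3), and 1185 and 437 (4-week replicates 1 and 2), and with an offset for transcript length it was 606.

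Most interferon genes were higher at 8 than at 4 weeks. The interferon response genes had 15 higher and 0 lower of 24 (17 and 0 adjusted over the list alone). The interferon list had a median of 1.06 and a camera adjusted p of 4.62e-11 (adjusted p = 0.462 with an estimated correlation). Ifi44 was at 2.46 ± 0.46, Ifit2 (chromosome 19, 34550694 to 34576419) at 1.22 ± 0.21 and Stat1 at 0.81 ± 0.11. Of the 18 Th1 genes, 3 were higher and 0 lower (3 and 0 adjusted over the list alone). For the Th1 list camera gave an adjusted p of 0.0283 (adjusted p = 0.466 with an estimated correlation, 0.0522 without 8-week ApoB+ replicate 1 and 0.945 without 4-week ApoB+ replicate 1, 0.0558 with only the 2 groups and 0.065 with DESeq2) at a median of 0.37. Among 15 Th17 genes, 2 were higher and 0 lower (3 and 0 adjusted over the list alone). The Th17 list had a median of 0.52 and a camera adjusted p of 0.031 (adjusted p = 0.466 with an estimated correlation, 0.0674 without 8-week ApoB+ replicate 2 and 0.457 without 4-week ApoB+ replicate 1, 0.143 with a stricter filter, 0.1 with only the 2 groups and 0.127 with DESeq2). The follicular helper (Tfh) genes had 2 higher and 0 lower of 16 (2 and 0 adjusted over the list alone). By camera the Tfh list did not pass (median 0.34, adjusted p 0.0972, or 0.00744 without 4-week ApoB+ replicate 2). The 2 called were Cxcr5 (0.96 ± 0.18) and the purine receptor gene P2rx7 (chromosome 5, 122643911 to 122691432) (1.18 ± 0.19). Of the 21 effector memory genes, 2 were higher and 6 lower (3 and 8 adjusted over the list alone). The effector memory list did not pass camera (median -0.08, adjusted p 0.21, or 0.000312 without 4-week ApoB+ replicate 1). Itgb1 (chromosome 8, 128685654 to 128733200) was at 0.79 ± 0.13, and the short transcripts of Crip1 (chromosome 12, 113146316 to 113153879) and Lgals1 (chromosome 15, 78926725 to 78930465) were at -1.23 ± 0.18 and -1.22 ± 0.21. Among 27 Treg genes, 1 were higher and 5 lower (2 and 6 adjusted over the list alone). By camera the Treg list did not pass (median -0.24, adjusted p 0.0972, or 0.0249 without 8-week ApoB+ replicate 3 and 1.35e-05 without 4-week ApoB+ replicate 1). Foxp3 did not pass (-0.24 ± 0.19, or 0.24 without 4-week replicate 2). Of the myeloid markers, Lyz2 stood at 26.3 and 26 CPM, while Cybb (chromosome X, 9435252 to 9487771) rose by 1.99 ± 0.29. The myeloid cell markers had 1 higher and 1 lower of 20 (1 and 1 adjusted over the list alone). The myeloid list did not pass camera (median -0.10, adjusted p 0.965).

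Most genes of energy and protein production on the lists were lower at 8 weeks. Of the 32 nuclear respiratory chain genes, 0 were higher and 32 lower (0 and 32 adjusted over the list alone). For the respiratory list camera gave an adjusted p of 6.49e-27 (adjusted p = 0.396 with an estimated correlation) at a median of -0.81. Atp5g1 (chromosome 11, 96068852 to 96075670), a subunit gene of ATP synthase, was at -0.84 ± 0.13 and Uqcrq (chromosome 11, 53427922 to 53430831) at -1.05 ± 0.18. Among 40 ribosomal protein genes, 0 were higher and 34 lower (0 and 39 adjusted over the list alone). The ribosomal list had a median of -0.67 and a camera adjusted p of 1.15e-19 (adjusted p = 0.462 with an estimated correlation). The proliferation genes had 0 higher and 6 lower of 25 (0 and 11 adjusted over the list alone). For the proliferation list camera gave an adjusted p of 2.13e-05 (adjusted p = 0.466 with an estimated correlation, 0.0687 without 4-week ApoB+ replicate 2) at a median of -0.57. The fold changes rose with transcript length (rho = 0.465 across 13155 genes). The median transcript was 5213.5 nt for genes called higher and 1321 nt for genes called lower. With an offset for transcript length, 5 of the 72 respiratory chain and ribosomal protein genes were lower, and their median was -0.13. Of the 2134 genes called at 8 against 4 weeks, 443 were still called with that offset.

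**Figure D4:**
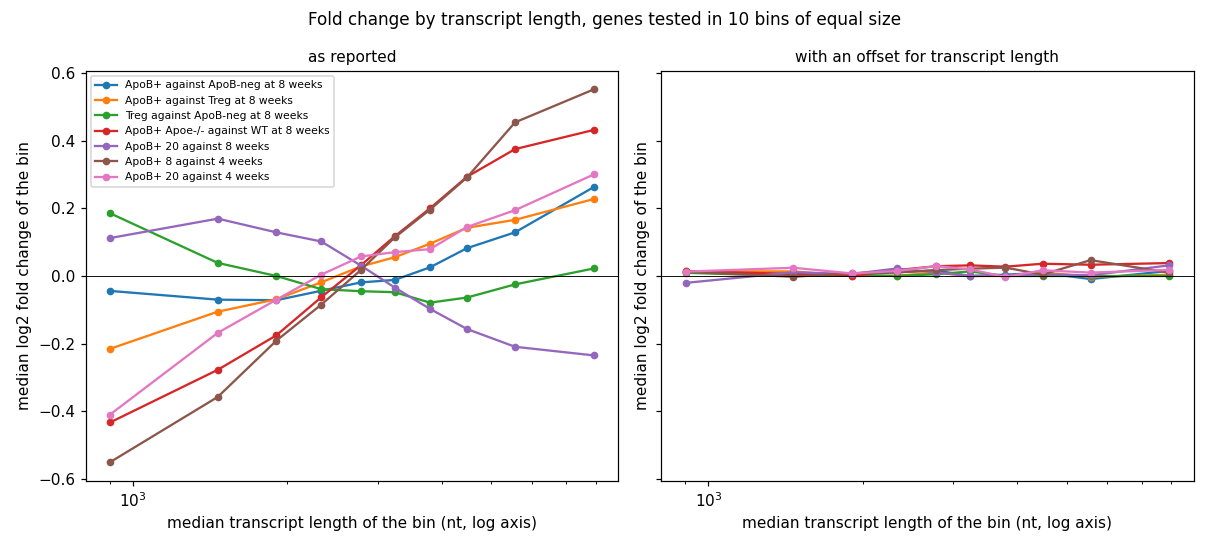
Median log2 fold change of the genes tested, in 10 bins of equal size by transcript length (nt, log axis), for each of the 7 comparisons, as reported (left) and with an offset for transcript length (right). The 8 against 4 week comparison and the Apoe-/- against WT comparison climb most with length (rho = 0.465 and 0.416 across genes).

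ApoB+ cells at 20 against 4 weeks spanned the whole age range. At 20 weeks 708 genes rose and 878 fell. Tmem176b rose by 3.58 ± 0.26 (adjusted p = 1.37e-06), from 14.8 ± 4.7 (SD, n = 2) to 176 ± 30.4 CPM (SD, n = 3). Asb2 (chromosome 12, 103321142 to 103356001), a ubiquitin ligase subunit gene, rose by 3.47 ± 0.23 (adjusted p = 8.19e-07), from 11.9 ± 3.28 (SD, n = 2) to 132 ± 23.4 CPM (SD, n = 3). Cxcr5 rose by 2.14 ± 0.19 (adjusted p = 8.32e-06), from 61.7 ± 9.08 (SD, n = 2) to 272 ± 41.5 CPM (SD, n = 3). Itm2a fell by 2.96 ± 0.23 on the log2 scale, from 365 ± 131 (SD, n = 2) to 47.1 ± 17.2 CPM (SD, n = 3), and the transcription factor gene Sox4 (chromosome 13, 28948919 to 28953713) by 3.07 ± 0.33. The paralogs Lilrb4 (chromosome 10, 51490956 to 51496611) and Gp49a (chromosome 10, 51480632 to 51486703), whose shared reads make the split between them uncertain, rose by 5.38 ± 0.52 and 5.79 ± 0.92. Apoe did not pass (-1.60 ± 0.53, adjusted p = 0.0597, or 0.0256 without 20-week replicate 3 and 0.0229 with DESeq2). Without 20-week replicate 3 the count of 1586 genes was 956, and without 4-week replicates 1 and 2 it was 781 and 658.

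Most Th17 genes and some Tfh genes rose over the whole age range, and some Treg genes fell. Of the 15 Th17 genes, 10 were higher and 0 lower (12 and 0 adjusted over the list alone). The Th17 list had a median of 2.69 and a camera adjusted p of 1.28e-16. Rora was at 1.16 ± 0.21 and Ccr6 at 1.91 ± 0.35. The Th17 cytokine gene Il17f (chromosome 1, 20777146 to 20790617) was at 7.35 ± 1.34, with 0.0782 ± 0.111 (SD, n = 2) and 13.3 ± 2.54 CPM (SD, n = 3). Among 10 gamma-delta and innate-like T cell markers, 3 were higher and 1 lower (3 and 1 adjusted over the list alone). The gamma-delta list had a median of 1.25 (0.65 with genes at 0 in 1 group set to their bound). Camera gave an adjusted p of 0.00353 (0.0643 with an estimated correlation). The follicular helper (Tfh) genes had 5 higher and 0 lower of 16 (8 and 1 adjusted over the list alone). The Tfh list had a median of 0.69 and a camera adjusted p of 7.01e-06. P2rx7 was at 1.48 ± 0.19. Of the 18 Th1 genes, 7 were higher and 0 lower (12 and 0 adjusted over the list alone). For the Th1 list camera gave an adjusted p of 1.72e-05 (adjusted p = 0.151 with an estimated correlation) at a median of 0.75. Stat4 (chromosome 1, 51987148 to 52107189), which transmits the interleukin 12 signal, was at 0.83 ± 0.13. Among 27 Treg genes, 2 were higher and 11 lower (2 and 13 adjusted over the list alone). The Treg list had a median of -0.44 and a camera adjusted p of 3.94e-08 (adjusted p = 0.151 with an estimated correlation). Foxp3 was at -1.50 ± 0.19, Lrrc32 at -2.35 ± 0.30 and Gpr83 at -1.59 ± 0.19.

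Other programmes shifted too. The naive and recirculating T cell genes had 1 higher and 10 lower of 18 (2 and 13 adjusted over the list alone). For the naive list camera gave an adjusted p of 4.88e-07 (adjusted p = 0.151 with an estimated correlation) at a median of -0.59. Sell was at -1.01 ± 0.16 and Ccr7 (chromosome 11, 99144196 to 99155077) at -0.88 ± 0.15, while Il7r rose by 1.39 ± 0.17. Of the 21 effector memory genes, 6 were higher and 2 lower (7 and 3 adjusted over the list alone). The effector memory list had a median of 0.12 and a camera adjusted p of 0.0139 (adjusted p = 0.577 with an estimated correlation, 0.232 without 20-week ApoB+ replicate 1 and 0.88 without 4-week ApoB+ replicate 1). Anxa1 was at 2.64 ± 0.32 and Cxcr6 at 2.21 ± 0.39. Among 20 early genes induced by the T cell receptor, 0 were higher and 4 lower (0 and 4 adjusted over the list alone). For the early list camera gave an adjusted p of 0.000853 (adjusted p = 0.172 with an estimated correlation) at a median of -0.28. Nr4a1 (chromosome 15, 101254269 to 101274795) was at -1.65 ± 0.27 and Myc (chromosome 15, 61985391 to 61990374), a growth regulator, at -0.92 ± 0.14. The proliferation genes had 0 higher and 5 lower of 25 (0 and 15 adjusted over the list alone). The proliferation list had a median of -0.74 and a camera adjusted p of 4.88e-07 (adjusted p = 0.216 with an estimated correlation). Of the 32 nuclear respiratory chain genes, 0 were higher and 25 lower (0 and 30 adjusted over the list alone). For the respiratory list camera gave an adjusted p of 3.86e-21 (adjusted p = 0.166 with an estimated correlation) at a median of -0.73. Among 40 ribosomal protein genes, 0 were higher and 33 lower (0 and 39 adjusted over the list alone). The ribosomal list had a median of -0.77 and a camera adjusted p of 2.04e-23 (adjusted p = 0.172 with an estimated correlation). With an offset for transcript length, 14 of the 72 respiratory chain and ribosomal protein genes were lower (median -0.23). The rho of fold change with transcript length was 0.278 here, and 0.21 and 0.215 for ApoB+ against ApoB-neg cells and Tregs. Of the myeloid markers, Cybb rose by 1.41 ± 0.29 (adjusted p = 0.0509 without 4-week replicate 1). The myeloid cell markers had 1 higher and 1 lower of 20 (1 and 1 adjusted over the list alone). By camera the myeloid list did not pass (median -0.10, adjusted p 0.553).

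Some lists did not pass camera as reported in any of the 7 comparisons, though some passed under other settings. The smallest camera adjusted p was 0.0605 for glycolysis genes (ApoB+ against ApoB-neg cells, 0.0057 without ApoB-neg replicate 3, 0.0318 with no filter, 0.0476 with a stricter filter, 0.00726 with a length offset, 0.0403 with limma-voom and 0.0392 with DESeq2). It was 0.076 for plasma cell markers (0.0348 and 0.0398 without ApoB-neg replicates 2 and 3, 0.0205 with no filter and 0.0403 with limma-voom) and 0.102 for dendritic cell markers. With a stricter filter the dendritic list passed for ApoB+ against ApoB-neg cells (0.00752), Tregs against ApoB-neg cells (0.0189, or 0.0328 with only the 2 groups) and 20 against 8 weeks (0.0185). For erythroid and platelet markers the smallest was 0.264 and for lymph node stromal and vessel markers 0.105 (0.0378 with no filter for 20 against 8 weeks). No gene of these last 2 lists was called in any comparison. The Apoe neighbours on chromosome 7 passed in 1 comparison, ApoB+ cells against Tregs. Of the 40 Apoe neighbours on chromosome 7, 0 were higher and 3 lower (0 and 0 adjusted over the list alone). The Apoe neighbour list had a median of -0.21 and a camera adjusted p of 0.0422 (adjusted p = 0.229 with an estimated correlation, 0.068 without 8-week ApoB+ replicate 1, 0.0782 without 8-week ApoB+ replicate 3 and 0.0559 without Treg replicate 2, 0.0784 with a length offset and 0.0648 with only the 2 groups). The sex-linked list had 1 gene tested and was left out of camera. That gene, Xist (chromosome X, 103460366 to 103483254), expressed from the inactive X chromosome of females, was higher at 20 than at 4 weeks (1.20 ± 0.33, adjusted p = 0.029, or 0.0663 with only the 2 groups, 0.119 without 20-week replicate 3 and 0.214 and 0.0525 without 4-week replicates 1 and 2).

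**Figure D5:**
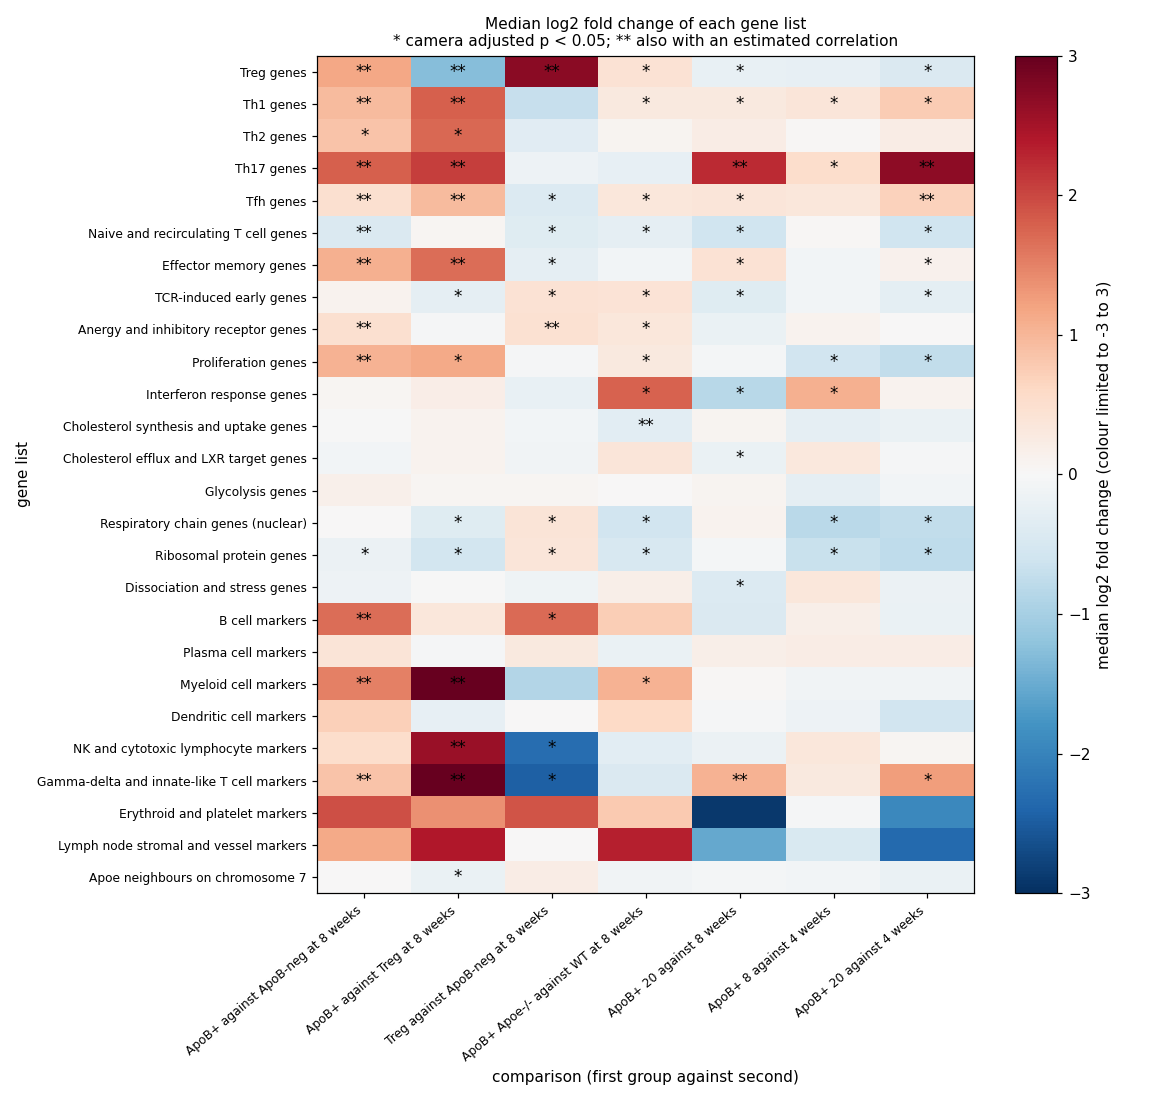
Median log2 fold change (colour, limited to -3 to 3) of 26 gene lists (vertical) in 7 comparisons (horizontal), with 1 star where camera's adjusted p is under 0.05 and 2 where this holds with an estimated correlation too. The Treg list is higher in ApoB+ than in ApoB-neg cells (median 1.15) and lower than in Tregs (median -1.28).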

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

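Tests of genes and lists and all alternatives were set before the data were examined, except the length offset and the lists without the sort genes (no call changed), chosen after the results were seen. The count of genes called stayed within 1.5 times in all 7 comparisons with RLE factors, upper-quartile factors, no filter and edgeR robust. The cause was not tested for the changes that follow. For ApoB+ against ApoB-neg cells (293) only the 2 groups compared gave 566 and DESeq2 723. For Apoe-/- against WT (1416) the length offset gave 658, only the 2 groups 3098 and DESeq2 2375. For 20 against 8 weeks (305) the stricter filter gave 498, limma-voom 622 and DESeq2 1006. For 8 against 4 weeks (2134) the length offset gave 606 and only the 2 groups 3279, and for 20 against 4 weeks (1586) only the 2 groups gave 397. The overlap of 128 became 197 with only the 2 groups and 284 with DESeq2. A replicate block gave 399 (Apoe-/- against WT), 494 (20 against 8 weeks) and 994 (8 against 4 weeks), although over all genes the numbers do not pair the samples: in the 8-week Apoe-/- groups same-number correlations ran from -0.00995 to 0.0477 over 9 pairs and others from -0.0681 to 0.0369 over 18, and not every sample correlated best with its own number. For 20 against 8 weeks all 3 did (0.0545 to 0.0674, others -0.0416 to -0.0219), a hint from the data, and the interferon list was lowest in replicate 3 of each 8-week Apoe-/- group. The block gained 7 list calls and lost 2. Leaving out 1 replicate gave 129 to 298, 1104 to 1732 (ApoB+ against Treg), 1169 to 1564 (Treg against ApoB-neg), 115 to 644, 93 to 1519, 437 to 1267 and 658 to 1873 genes, in the order of the report, and an overlap of 63 to 126. The lone sample left of a pair is assumed to vary like the other groups. With an estimated correlation, lists past the threshold numbered 8 (ApoB+ against Treg), 2 (Treg against ApoB-neg), 1 (Apoe-/- against WT), and 2, 0 and 2 over the ages (20 against 8, 8 against 4, 20 against 4). The interferon list for ApoB+ against ApoB-neg cells changed direction and passed without 8-week ApoB+ replicate 3 (adjusted p 0.0422, highest 0.797 without ApoB-neg replicate 2). With the length offset Rpl13 changed sign for Apoe-/- against WT (log2 0.00595), and Rpl13 (0.0138), Cst3 (0.0663) and Gemin7 (0.0124) did for 8 against 4 weeks. Of 1229 gene results, 1219 kept sign and call with edgeR robust, 1214 with RLE factors, 1190 with upper-quartile factors, 1188 with no filter, 1127 with limma-voom, 1081 with the block and 1064 with the length offset. Where the gene was tested, 1048 of 1172 did with DESeq2, 977 of 1155 with only the 2 groups and 928 of 974 with the stricter filter.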

Other observations

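The tests on the Treg and interferon genes below, the comparison of WT ApoB+ with ApoB-neg cells and the offset for transcript length were chosen after the results were seen. The predictions for length and GC content and the splits were written before those tests were run. Below, SE beside a list median is the median SE of its genes and does not measure the error of that median. Ltb4r1, P2ry1 and Ryr1 were chosen after their values were seen. Ltb4r1, a receptor for leukotriene B4, stood at 2.83, 3.85 and 18.2 CPM at 4, 8 and 20 weeks, against 0.407 in ApoB-neg cells and 0.644 in Tregs. P2ry1 stood at 6.96, 14.9 and 26.1 CPM and Ryr1 at 12.7, 15.1 and 39.1. Il17re (chromosome 6, 113458484 to 113470758), a receptor chain for interleukin 17C, rose by 3.87 ± 0.68 from 4 to 20 weeks and the guidance receptor gene Unc5a (chromosome 13, 54949411 to 55006018) by 3.48 ± 0.66. Arnt2 (chromosome 7, 84246278 to 84410176), a transcription factor gene, rose by 7.01 ± 1.33 (from 0.155 to 20.5 CPM) and the protease inhibitor gene Serpina9 (chromosome 12, 103994743 to 104013755) by 6.66 ± 1.03 (from 0.172 to 17.7 CPM).

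WT ApoB+ cells held Treg genes above the ApoB-neg level too, with Foxp3 higher by 1.76 ± 0.20 (adjusted p = 0.000216), at 170.2 against 50.3 CPM, and 14 of the 27 genes on the fixed Treg list higher against the same 3 ApoB-neg libraries. Klrg1 stood at 21.1 CPM in WT ApoB+ cells and 3.4 in ApoB-neg cells, and Cd209b at 8.84 and 1.48. Genotype differs between these groups as well, and Tregs may have been sorted out of the ApoB-neg cells.

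In 3 against 3 libraries only 10 splits exist, too few for a share under 0.05. The real split called 293 (ApoB+ against ApoB-neg), 1781 (ApoB+ against Treg), 1628 (Treg against ApoB-neg) and 305 genes (20 against 8 weeks), the highest other 0, 0, 1 and 0, so 1 split of each 10 gave as many.

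Treg genes were higher in ApoB+ than in ApoB-neg cells at 8 weeks, with 20 of 27 called. A larger share of Tregs like the sorted ones cannot be told apart from Treg genes in other ApoB+ cells. Of the 18 Treg genes higher in both ApoB+ cells and Tregs, sort genes aside, 10 lay over 2 SE from the median share of 27.8% (15.8% for Foxp3, 95.5% for Tigit), but these shares assume the ApoB-neg profile in all other ApoB+ cells, and 13 of 21 effector memory genes were higher than that. Myeloid cells with Lyz2 would leave WT ApoB+ cells, whose Lyz2 is near that of ApoB-neg cells (0.0862 ± 0.449), without the Treg genes. Yet the median of the fixed list of 27 there was 0.723 (median gene SE 0.205) against the same 3 ApoB-neg libraries. Lyz2 does not mark every MHC class II cell, so other such cells were not tested. Tregs like the sorted ones, Tregs of another activation state, other ApoB+ cells with Treg genes and MHC class II cells without Lyz2 stay open. So does a sort that took Tregs out of the ApoB-neg cells (Foxp3 at 50.3 CPM, against 1188 in sorted Tregs), which would act on the WT values too.

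Interferon response genes were higher in Apoe-/- than in WT ApoB+ cells at 8 weeks, with a median of 1.76. WT cells were sequenced at 8 weeks only, and genotype may account for all or part of the difference. Over these WT cells the median was 0.87 (SE 0.307, 1 of 24 called) at 4 weeks, or 1.27 and 0.441 without 4-week replicates 1 and 2. At 20 weeks it was 0.841 (SE 0.281, 13 of 24 called), or 0.821 and 0.799 without WT replicates 1 and 2. Without each 20-week replicate in turn, 10 of the 24 were called. The Apoe genotype alone, with no change with age, would give as much at 4 as at 8 weeks. Yet 8 against 4 weeks had a median of 1.06 (SE 0.282, camera adjusted p = 0.462 with an estimated correlation), or 0.806 (SE 0.332) without 4-week replicate 1. The difference of library means was 1.03 ± 0.278 (4-week libraries at 5.78 and 6.54, 8-week ones from 6.76 to 7.46). Without WT cells of 4 weeks, a rise with age in both genotypes stays open. These values therefore do not decide whether genotype gives the whole 8-week difference. Myeloid cells with Lyz2 among the ApoB+ cells would spare sorted Tregs, whose Lyz2 is below that of WT ApoB+ cells (-1.82). Yet the median of the list in Tregs over WT ApoB+ cells was 1.58 (SE 0.294). Dendritic cells without Lyz2 were not tested. A difference between the 8-week Apoe-/- cohort and the other cohorts (mice, day or library batch) cannot be told apart from age and genotype, which could act on all T cells of these mice: within that cohort the median was 0.0602 (SE 0.248) for ApoB+ against ApoB-neg cells and 0.20 for ApoB+ cells against Tregs (camera adjusted p 0.35, or 0.00709 without ApoB+ replicate 3), and the labels give no batch.

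Respiratory chain and ribosomal protein genes were lower in ApoB+ cells at 8 than at 4 weeks, with 66 of 72 called and a median of -0.765 (SE 0.181). A trend with GC content between the libraries is argued against, since the median stayed at -0.729 with 57 genes lower after that trend was taken out. With a trend in transcript length taken out 5 genes were lower. The median was then -0.132 (median SE of the genes 0.12), over 1 but under 2 of those SEs from 0. Library or RNA quality that favours long transcripts and a fall of these short transcripts with age cannot be told apart here, since both lists hold short transcripts and age groups may differ in preparation. Age stays among the open explanations, as untested.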
